A study of Homo sapiens with 6 samples.

How the data were processed

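The study transfected HaCaT cells, an immortalised human keratinocyte line, with siRNA against NCSTN or with a mismatch control siRNA. Each well received 100 pmol of siRNA, and total RNA was taken 72 hours (day 3) later, per the labels' protocols. The RNA was labelled with Cy3 and hybridised to one-colour Agilent whole-genome arrays. The labels give 3 samples per group, and each sample has its own scanner file.

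The scanner files hold spot intensities that the authors deposited as Agilent Feature Extraction wrote them. Per the file headers the processed intensity of a spot is background-subtracted and detrended within the array, and it is not scaled between arrays. The file headers name Feature Extraction version 11.0.1.1, while the submitters' processing notes name version 9.1, and nothing in the sources used here settles which of these applied. The other columns used were the median spot and local background intensities and the flags for outlier, saturated and background-outlier spots and for spots well above background, per the file headers. A table of processed values that the authors deposited for the same 6 samples is on a log2 scale and holds 26411 probes. Its column medians were 8.40 in each of the 6 samples, with quartiles near 6.34 and 10.9, and its probe differences correlated at r = 1.00 with those of the quantile-normalized scanner values across probes. Its normalization and probe filter are not given in the sources used here. The table served as an alternative.

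Before any averaging the 6 files were compared spot by spot. On 999 probes printed 10 times each, the deviation of every spot from its probe's mean was correlated between files, over 7473 spots that were well above background and free of outlier flags in all 6. The correlation was 0.843 to 0.918 in the 6 pairs of files from the same group and 0.357 to 0.390 in the 9 pairs from different groups. After the other group's mean deviation was regressed out, the correlation within a group was still 0.815 to 0.903. Spots whose local background was an outlier were shared 16.8 to 51.2 times as often as chance gives within a group, against 0.609 to 4.50 times across groups. Array positions in the file headers were the same for the 3 files of a group and differed between the groups. The 3 files of a group were therefore treated as 3 scans of 1 hybridised array, and each group as n = 1 array. The replicate numbers in the labels were taken to number these scans.

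The test fixed before the data were examined was a limma fit over 6 samples, with camera for the gene lists and an exact permutation test for NCSTN. With 1 array per group no test between the groups exists, because the fit would measure only the spread between scans. The main results are therefore differences between the 2 arrays, called by a fixed size rule of 2-fold (1 on the log2 scale), and no p-value is given. The limma and camera counts over the 6 scans appear among the alternatives. Counts over other splits of the samples need several arrays per group and were not made.

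Main values were log2 of the processed intensity minus the 75th percentile of the array's non-control spots. Of the 44495 spots of an array, 1377 were control spots and were left out, as were spots with an outlier flag (354 to 433 per scan). Replicate spots of a probe were averaged, which left 34127 probes. Between 76.1% and 79.2% of the non-control spots of a scan were well above background, and no spot was saturated. A probe was tested when it was well above background on all 3 scans of at least 1 group, which 26090 probes were. Probes were named by matching their transcript accession, without version, to a RefSeq gene table of assembly GRCh38.p14. A symbol was found for 25767 probes and 19736 genes, and 8360 probes stayed unnamed. The array design refers to hg19 (GRCh37), per the file headers, so no coordinates are given. A gene was represented by its brightest tested probe, which gave 16270 genes. Values of 29 genes on the Y chromosome or in the X-inactivation centre are not reported. IFI27 and UBE2C, members of 2 of the lists, were not analysed here.

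The error given with a difference is the SD over the 3 scans, which covers scanning only. The noise of single spots was estimated from the repeated probes. A difference between the 2 arrays for a probe printed once has a 95% limit of 1.30-fold among the dimmest of 4 equal groups of these probes and of 1.14-fold, 1.12-fold and 1.11-fold in the next groups. These limits cover neither the variation between cultures nor that between labelling reactions, and the number of arrays limits the precision of every value. The first limit pools probes from −5.91 to −2.50 on the log2 scale and may be too low for the dimmest. At −5.59 and −5.64, 2 control probes without a human target had spot SDs of 0.32, against 0.19 for that group. Another such control probe, at −6.18 and well above background in 32.8% of its spot readings, had 0.50. A 2-fold difference at such brightness may thus lie near the spot noise. Where a gene was not well above background on any scan of 1 group, its difference is given as "at least" a fold. That bound sets the brighter array's mean against the dim array's mean of, per scan, the higher of the lowest signal among probes well above background and the probe's own signal. It applies to the main values only, makes no allowance for spot noise and is not a guaranteed minimum.

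The 20 gene lists and the rule for named genes were fixed before the data were examined. The rule names the gamma-secretase subunits and the 12 genes with the largest difference in each direction among genes well above background on all scans. It adds up to 4 genes in each direction by the at-least fold and up to 3 members in each direction of each list. In the rule the limma fit over scans (adjusted p under 0.05) served as a filter on scan noise alone. It named 147 genes, and 33 more were chosen after their values were seen, among them HES1, HES2, HES4, NOTCH1, IVL, FLG, KRT1, KRT10, CALML5, GRHL3 and the claudin, kallikrein, metallothionein and SNHG genes of the closing section. For each list the median difference was set against 10000 random lists of the same size, matched in 20 bins of brightness. Its percentile among them describes these 2 arrays and is not a test of the siRNA. A list is called apart when its median lies outside the central 95% of the random lists. With genes at their bounds in place of their measured differences, no list's median changed.

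The size rule was tested on simulated data for the comparison of the NCSTN siRNA array with the control array, with 16270 genes carrying the measured spot and scan noise only, which leaves out variation between cultures. At that noise these folds lie far from the 2-fold rule, so the outcome checks the computation and not the rate of false calls. All 50 genes simulated at each of 3-fold, 4-fold and 8-fold were called (100%), no gene simulated at 1.5-fold was called (0.0%), and 0.0% of 16070 unchanged genes were called. Of 200 random lists of 20 genes drawn from the measured differences, 7.0% fell outside the central 95%, and 100% did once a shift of 0.4 was added.

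The alternatives were quantile normalization, median centring, normexp background correction (offset 50), the authors' value table, no filter on dim probes, a filter for probes well above background on all 6 scans, the mean of a gene's probes, and leaving out each scan. The files hold no mean spot intensity, so normexp used the median spot and background intensities. The slide as a block was not run: files with the same replicate number share 1 scan image in both groups, per the file headers, so the files give no slide apart from the scan. Size rules of 1.5-fold and 3-fold were added after seeing the data. Software was R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8), and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.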

Results

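Gene expression was profiled in HaCaT keratinocytes 72 hours after transfection with siRNA against NCSTN, which encodes nicastrin, a subunit of the gamma-secretase protease that cleaves Notch receptors. The comparison was with cells given a mismatch control siRNA, and it asked which transcripts differ once NCSTN is silenced. The labels list 3 samples per group. Their scanner files shared spot-level deviations within each group (r = 0.843 to 0.918) far more than between groups (r = 0.357 to 0.390), so the 3 files of a group were counted as repeat scans of 1 array. The median processed signal of a scan was 176 to 198 and its 75th percentile 1524 to 1612. In each group both were lowest on scan 1 and highest on scan 2. Differences are given as NCSTN siRNA minus control on the log2 scale with n = 1 array per group, with the SD over 3 scans. That SD covers scanning error only. No difference has a replicate check, and none carries a p-value.

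**Figure D1:**
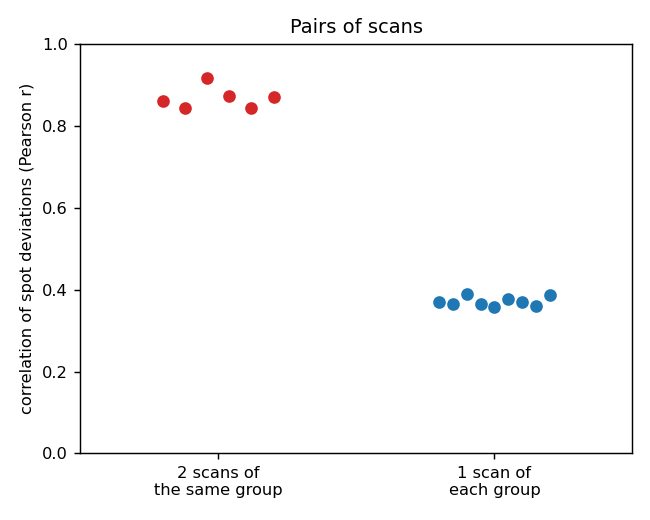
Correlation (Pearson r, y axis) of spot deviations from the probe mean, over 7473 spots of probes printed 10 times, for each pair of scans (points). The 6 pairs within a group lie at 0.843 or above and the 9 pairs across groups at 0.390 or below.

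NCSTN was 4.08-fold lower on the NCSTN siRNA array (−2.03 ± 0.02), against a 95% limit of single-spot noise of 1.14-fold or less at its brightness. It was the only gamma-secretase subunit past 2-fold. PSEN2, a catalytic subunit, differed by −0.32 ± 0.02. APH1A (−0.07 ± 0.01) and PSENEN (−0.02 ± 0.05) lay within the spot noise, and the sign of APH1A turned with the mean of its 2 probes and that of PSENEN with normexp. APH1B was higher by 0.77 ± 0.02, which is 1.71-fold. The 6 subunits had a median of −0.11, at percentile 8.52 of random lists.

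Notch target genes were lower as a list. Of 16 tested targets 11 were lower and 5 higher, with a median of −0.12 at percentile 1.06 of brightness-matched random lists, and 2 were lower and 1 higher by at least 2-fold. HES5, a Notch-induced transcriptional repressor, was 3.70-fold lower (−1.89 ± 0.03), and NRARP, a feedback inhibitor of Notch, was 2.24-fold lower (−1.17 ± 0.04). NOTCH3, a receptor that is itself a Notch target, was lower by 1.86-fold. HES2 (−0.86 ± 0.03), HES4 (−0.81 ± 0.02), MYC (−0.68 ± 0.00) and HES1 (−0.48 ± 0.03) were lower by less than 2-fold. HEY1 was higher by 0.37 ± 0.01, and HEYL, at 0.23 ± 0.05, lay within the spot noise. DTX1, a ubiquitin ligase that modifies Notch signalling, was not well above background on the control array and was at least 5.58-fold higher on the NCSTN siRNA array. Among 27 tested Notch receptors, ligands and modifiers 14 were higher and 13 lower, with a median of 0.02 at percentile 19.4 that was −0.06 with quantile normalization. MIB1, which ubiquitinates Notch ligands, was at −0.55 ± 0.01 and NOTCH4 at 0.51 ± 0.04. NOTCH1 read 0.41 by its brightest probe, but the mean of its probes was −0.07.

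**Figure D2:**
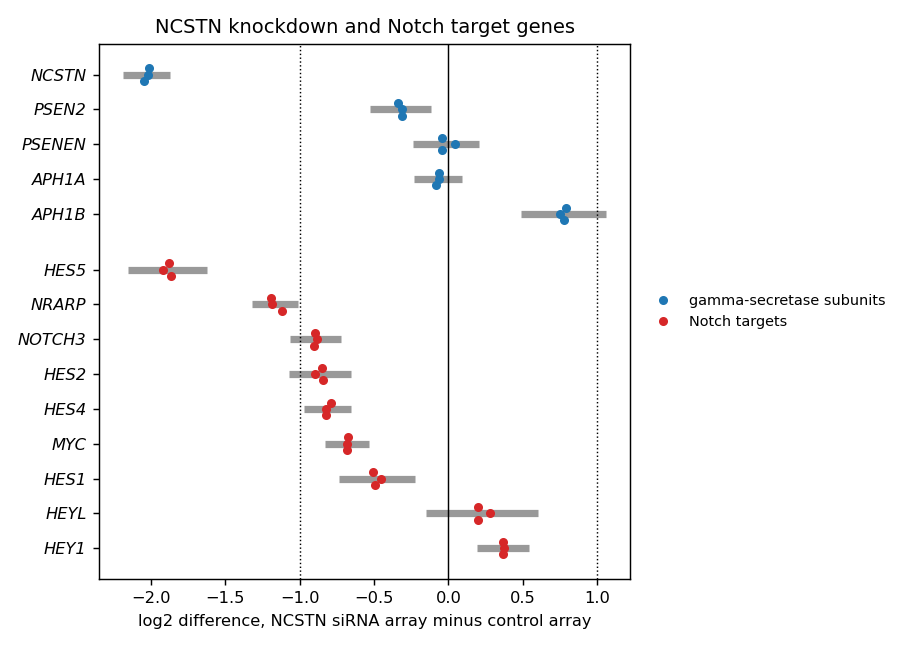
Log2 difference between the NCSTN siRNA and control arrays (x axis) for named gamma-secretase subunits and Notch targets, with a point for each of the 3 scans. Grey bars are 95% limits of single-spot noise around the mean and dotted lines mark 2-fold. NCSTN, HES5 and NRARP lie beyond the line at −1.

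Keratinocyte differentiation genes held the most 2-fold differences of the 20 lists. Of 49 tested genes of terminal differentiation and the cornified envelope, 31 were lower and 18 higher. Their median of −0.29 lay below all 10000 random lists (central 95%, −0.02 to 0.17). At least 2-fold lower were 11 members, against a mean of 0.618 in the random lists, and no member was 2-fold higher. Of these 11 members 3 had a second tested probe, which was also below −0.5 for 2 of them. Related members may vary together, which the random lists do not allow for: the SPRR family held 4 2-fold-lower genes among 10 tested. KLK13, a serine protease, was 3.17-fold lower (−1.66 ± 0.01) and the keratin KRT4 3.14-fold lower (−1.65 ± 0.02). SBSN, which encodes suprabasin, was not well above background on the NCSTN siRNA array and was at least 4-fold lower. CALML5, a calcium-binding protein of differentiating keratinocytes, was at −1.47 ± 0.07, and at −0.96 with normexp. GRHL3, a transcription factor of barrier formation, was at −1.26 by its brightest probe and −0.59 by the mean of its probes. The small proline-rich genes SPRR2E (−1.24 ± 0.02) and SPRR2A (−1.14 ± 0.01) were also past 2-fold. IVL, which encodes the envelope precursor involucrin, was at −0.94 ± 0.04, KRT1 at −0.57 ± 0.02 and KRT10 at −0.26 ± 0.03. Other members went the opposite way: PRDM1 was higher by 0.89 ± 0.06, SPRR2G by 0.78 ± 0.03, LCE3D by 0.76 ± 0.03 and FLG, which encodes filaggrin, by 0.63 ± 0.03.

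Keratins and S100 proteins of activated keratinocytes were lower too, with 10 of 13 members below 0 and a median of −0.40, also below all random lists. With quantile normalization their median was −0.27, at percentile 0.01. PI3, the elastase inhibitor elafin, was 2.12-fold lower (−1.08 ± 0.04), KRT16 was at −0.91 ± 0.05, KRT6B at −0.89 ± 0.02 and KRT6A at −0.40 ± 0.01. S100A7A was at 0.24 ± 0.06, SERPINB3 at 0.23, and SERPINB4 at 0.13 with the sign turned only under median centring, which lowers every probe alike. The 16 basal and hemidesmosome genes had a median of −0.18 inside the random range (percentile 6.55), and of −0.04 with quantile normalization. Within it KRT5 (−0.62 ± 0.01), KRT15 (−0.61 ± 0.02) and TP63 (−0.54 ± 0.03) were lower, while DST (0.49 ± 0.00), COL7A1 (0.36 ± 0.02) and ITGB4 (0.30 ± 0.02) were higher.

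**Figure D3:**
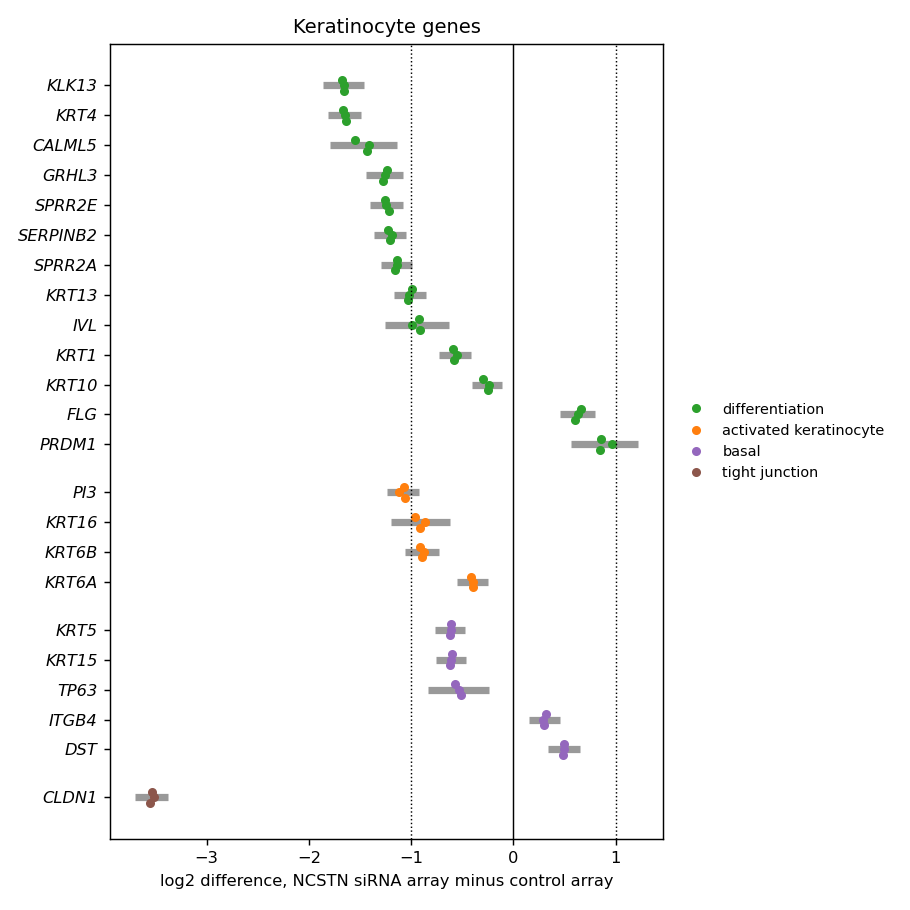
Log2 difference between the arrays (x axis) for named keratinocyte genes, with a point per scan, grey 95% limits of single-spot noise and dotted lines at 2-fold. CLDN1 lies at −3.54, and 8 of the 13 differentiation genes drawn lie at or beyond −1.

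Inflammatory genes were lower as a list, with 18 of 30 below 0 and a median of −0.09 at percentile 0.200, and of −0.03 with normexp. CSF2, which encodes a granulocyte and macrophage growth factor, was 2.79-fold lower but at −0.66 with normexp. IL1B was at −0.97 ± 0.01, IL36G at −0.93 ± 0.03 and IL1RN, the interleukin-1 receptor antagonist, at −0.92. DEFB4A (0.74 ± 0.01), CXCL3 (0.73 ± 0.04), IL36A (0.71 ± 0.08) and IL6 (0.69) were higher. The 42 interferon-stimulated genes split evenly, 21 higher and 21 lower, with none past 2-fold and a median of −0.01 at percentile 13.0 that turned positive with normexp. OAS2 read 0.57 by its brightest probe, with another of its 3 probes at −0.23, and HERC5 was at −0.57.

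Genes of the cell cycle stood slightly higher than genes of like brightness. Their median was 0.07 at percentile 99.9 of random lists, whose middle was −0.06, and 30 of 43 members were above 0. The median was 0.16 with quantile normalization and −0.06 under median centring, which lowers every probe alike. CCNE1 (0.50 ± 0.01), MCM5 (0.50 ± 0.01) and PLK1 (0.34 ± 0.02) were higher. RRM2, a subunit of ribonucleotide reductase, went against the list at 2.30-fold lower (−1.20 ± 0.01), as did CDC6 (−0.80 ± 0.02). The 21 p53 targets had a median of 0.17 (percentile 92.1; −0.01 in the authors' value table), with SESN2 at 0.53 and GADD45A at −0.37.

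Genes of the unfolded protein and integrated stress responses had a median of −0.13 at percentile 1.68, with 18 of 28 below 0. PDIA4, a disulphide isomerase of the endoplasmic reticulum, was 2.28-fold lower (−1.19 ± 0.01), HERPUD1 lay just short of 2-fold lower, ATF4 was at −0.58, while SLC7A11, the cystine transporter, was higher by 0.91 ± 0.01. ATF3 read 0.76 by its brightest probe and −0.96 by another. This list lay inside the random range with quantile normalization (percentile 2.57), normexp (3.71) and the authors' value table (3.93). Sebocyte and hair follicle genes had a median of −0.14 at percentile 1.54. LHX2, a transcription factor of the hair follicle, was at least 3.37-fold lower, but at −0.77 with normexp. This list lay inside the random range with quantile normalization (3.62), in the authors' value table (3.81) and with only genes well above background on all scans (89.2). That last filter drops genes that are near background on 1 array: 17 of 20 members stayed, and 2-fold-lower members went from 3 to 0. It thus selects on the difference itself, so the 89.2 does not test this list.

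The other lists lay inside the random range in the main setting. The median was 0.04 for 22 other gamma-secretase substrates (percentile 74.1), 0.05 for 32 genes of the PI3K and AKT pathway (67.1) and 0.03 for 20 genes of the EGF receptor family and its feedback (28.2). It was 0.09 for 30 extracellular matrix and mesenchymal genes (52.3), 0.03 for 23 cholesterol genes (94.5), 0.06 for 24 lysosome and autophagy genes (96.2), −0.12 for 21 immediate early and heat shock genes (8.17) and 0.34 for 19 markers of other skin cell types (93.8). The median of the immediate early list was 0.00 in the authors' value table. With quantile normalization the median was 0.14 for the markers of other skin cell types and 0.03 for the matrix and mesenchymal genes. Single members stood out. Among the substrates EFNB1, an ephrin ligand, was 2.05-fold lower, at −0.96 with quantile normalization, and CDH2, N-cadherin, was higher by 0.69 ± 0.01. In the PI3K list PIK3R3 was higher by 0.88 ± 0.09 and no gene passed 2-fold. The metalloproteases MMP7 and MMP1 were 3.67-fold and 2.41-fold lower, and TGFB2, a growth factor, was 4.44-fold higher from a dim control signal. VIM, a mesenchymal intermediate filament, was not well above background on the control array and was at least 2.54-fold higher, but at 0.68 with normexp. FOSB was 2.60-fold lower, but at −0.61 with normexp, and JUN was higher by 0.72 ± 0.02. COL1A1, a fibroblast collagen, was 2.36-fold higher but dim on both arrays, and at 0.61 with normexp.

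**Figure D4:**
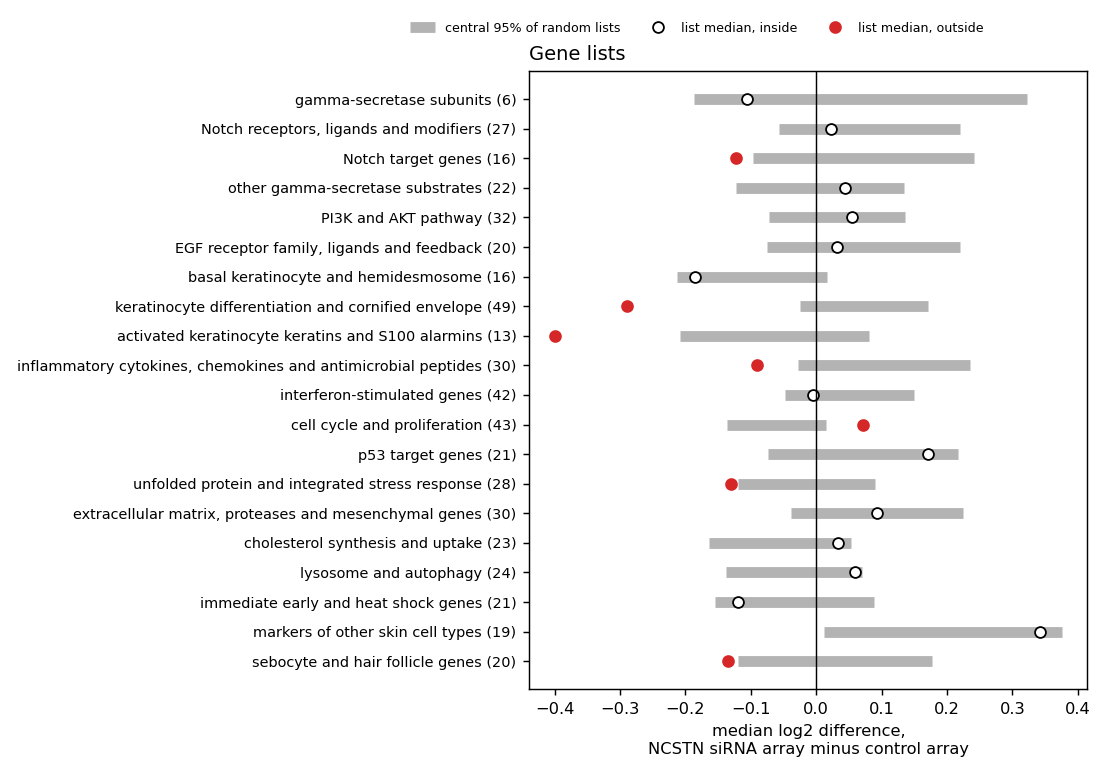
Median log2 difference of each gene list (points, number of tested genes in brackets, x axis) and the central 95% of 10000 brightness-matched random lists (grey bars). The 7 filled points lie outside their bars in the main setting, led by the activated keratinocyte list at −0.40 and the differentiation list at −0.29. With quantile normalization these 2 medians were −0.27 and −0.34.

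Across all genes 634 of 16270 differed by at least 2-fold, 354 higher and 280 lower, each by its brightest probe. Of the 53 with several tested probes, 14 had a second probe past 2-fold and 17 had probes that differed in sign. Among genes well above background on all scans 157 were higher and 153 lower. Counted by probe, 1110 of 26090 passed 2-fold, 624 higher and 486 lower. The split depended on the scaling: 56.2% of the probes past 2-fold were higher in the main setting, against 42.1% with quantile normalization, 44.2% with median centring, 40.2% with normexp and 41.8% in the authors' value table. The median of all tested probes was 0.09 and moved by −0.13 under median centring. The calls gathered among dim probes, with 349 higher and 211 lower in the dimmest of 10 equal brightness groups against 3 and 15 in the brightest.

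**Figure D5:**
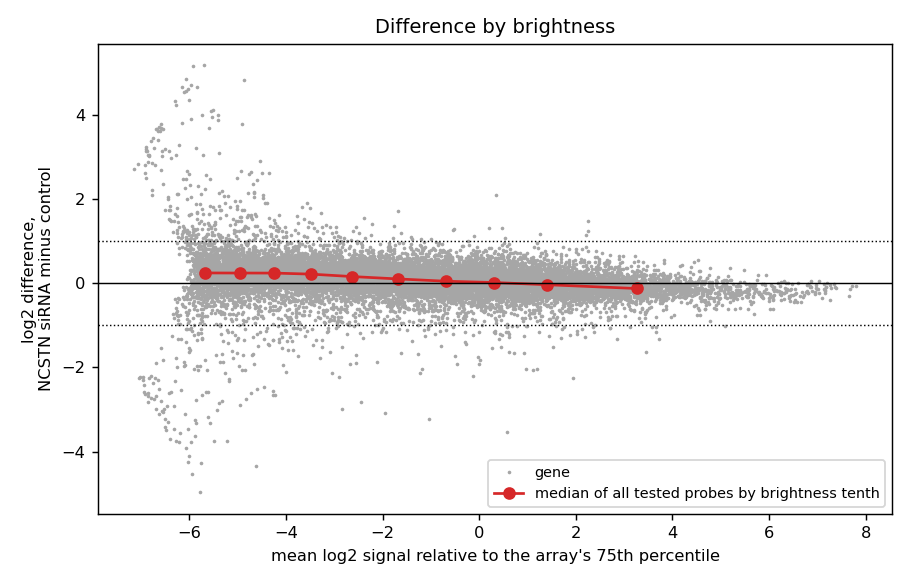
Log2 difference (y axis) against mean log2 signal relative to the 75th percentile (x axis) for every gene (grey), with the median of all tested probes in each of 10 brightness groups (red) and dotted lines at 2-fold. The median runs from 0.24 in the dimmest group to −0.12 in the brightest.

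The largest difference among genes well above background on all scans was in CLDN1, which encodes the tight-junction protein claudin-1 and was 11.6-fold lower (−3.54 ± 0.02). GALNT2, a glycosyltransferase, was 9.32-fold lower and RHPN1 was at −3.09 ± 0.08. They were followed by PARD6G-AS1, whose second probe was at −0.02, then MAB21L4 (7.10-fold), C1QTNF9B (6.31-fold), TBXAS1, the thromboxane synthase (5.87-fold), CCDC86 (4.79-fold), the ubiquitin-like UBD (4.65-fold), S100P (4.59-fold), OLFM4 (4.36-fold) and PRAC1 (4.35-fold). Genes with the largest differences upward were nearly all dim in the control. RFTN2 was 6.19-fold higher, UPP2 6.16-fold, TNIP3 5.46-fold, TNP2 4.52-fold, MBNL1-AS1 4.41-fold, HAAO 4.28-fold (its second probe at 0.86), DISP3 4.14-fold, FUCA2 4.08-fold, GYPB 3.86-fold and LINC01343 3.75-fold. With normexp MBNL1-AS1, DISP3, GYPB and LINC01343 no longer passed 2-fold. The exception was NR5A1, a steroidogenic transcription factor, 4.30-fold higher at −0.70 ± 0.02 on the control array and 1.41 ± 0.01 on the NCSTN siRNA array. Among genes not well above background on 1 array, ZNF608 was at least 11.3-fold lower, LINC01305 6.33-fold, ZBTB8B 6.15-fold and KRTAP20-3 5.51-fold, while C5AR2, a complement receptor, was at least 13.6-fold higher, CSN3 9.13-fold, KCNJ3 8.59-fold and DEFB126 7.27-fold.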

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

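The size rules of 1.5-fold and 3-fold, and the use of a size rule in place of the fit, were chosen after the data had been seen. NCSTN stayed at least 2-fold lower in all 13 settings tried, from −2.16 with median centring to −1.97 with normexp, −2.04 to −2.02 without 1 scan, with a main value of −2.03. The cause of the median-centring value is its construction, a shift of −0.13 for every probe. The number of probes changed after NCSTN siRNA, 1110 past 2-fold, was 1118 to 1168 without 1 scan (probes at least 2-fold higher 604 to 686, probes at least 2-fold lower 482 to 559). It was 249 with normexp (100 higher, 149 lower), which changes both the intensities used and the offset, 1968 without a filter on dim probes (1237 higher, 731 lower) and 474 with probes well above background on all scans (249 higher, 225 lower). It was 3337 at 1.5-fold (2201 higher, 1136 lower) and 516 at 3-fold (266 higher, 250 lower). Quantile normalization shared 918 of the main calls and normexp 248.

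Counted by the limma fit over the 6 scans, probes changed after NCSTN siRNA numbered 22225 at adjusted p under 0.05 (13914 higher, 8311 lower) and 20062 under 0.01 (12584 higher, 7478 lower). They numbered 8438 in the test against 1.2-fold (5752 higher, 2686 lower), 22560 with a trend and robust prior (14092 higher, 8468 lower) and 21843 with a replicate block (13674 higher, 8169 lower). Here probes at least 2-fold higher and probes at least 2-fold lower are replaced by probes past the p threshold in each direction. These counts measure the spread between scans of 2 arrays, not between cultures. Same-numbered scans did not deviate together (r = 0.03, 0.01 and 0.01 across probes), but r omits shifts of a whole scan. The slide as a block was not run, as files give none apart from the scan.

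Of the 20 lists 7 lay apart in the main setting, where 1 is expected from lists of unrelated genes. Genes of a list may vary together and some lists share members, so 7 against 1 does not measure chance. The Notch target, differentiation, activated keratinocyte, inflammatory and cell cycle lists, 5 in all, lay apart in each of the 13 other settings. The sebocyte list lay inside the random range with quantile normalization (3.62) and the authors' value table (3.81). It went from percentile 1.54 to 89.2 with genes well above background on all scans. That filter drops 3 of 20 members, all 2-fold lower, so it is no test. The lists of other skin cell types (98.4 with normexp) and of lysosome and autophagy (98.8 with the mean of a gene's probes) lay outside. Over the 6 scans camera called 2 lists with the preset correlation, 2 with a replicate block, 3 with an intensity trend and 0 with the correlation estimated, and fry called 19. The cause of these differences was not tested.

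Of 179 other named genes none that passed 2-fold changed sign, and 18 of the 64 past 2-fold fell short of it in some setting, most often normexp, among them CSF2, FOSB, VIM, COL1A1, LHX2 and CALML5. EFNB1, KRT13 and KRT8 did so with quantile normalization, and GRHL3 with the mean of its probes. PSENEN, APH1A, SERPINB4, NOTCH1 and CLDN4 changed sign in 1 or more settings, SERPINB4 only under median centring, which lowers every probe alike. EGF, 2.01-fold higher in the main setting, was short of 2-fold with quantile normalization (0.79), median centring (0.87), normexp (0.53), the authors' value table (0.79) and without NCSTN siRNA replicate 2 (0.86) or 3 (0.87). Signal over background limits the dim genes: single-spot noise was 1.30-fold in the dimmest of 4 groups of repeated probes. That limit may be too low for the dimmest probes.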

Other observations

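The gene families and the tests in this part were chosen after the results had been seen. Kallikreins, serine proteases of which several act in the shedding of the stratum corneum, were lower as a family. Of 13 tested members 9 were below 0, with a median of −0.53 under all 10000 random lists, and of −0.33 with normexp. KLK10 was 4.11-fold lower (−2.04 ± 0.04), KLK11 3.75-fold lower (−1.91 ± 0.01) and KLK7 was at −0.96. The 45 keratin genes and pseudogenes had a median of −0.25 with 29 below 0. The simple-epithelium keratins KRT8 (−1.04 ± 0.01) and KRT18 (−0.54 ± 0.01) were lower alongside KRT4 and KRT13. Claudins did not shift as a family: the median of 18 was 0.05, and −0.04 with quantile normalization. 3 members were past 2-fold lower, among them CLDN1 and CLDN8 (−1.70 ± 0.04), while CLDN7 was at −0.64 and CLDN4 at −0.02, with the sign of CLDN4 turned by quantile normalization.

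Metallothioneins, zinc-binding proteins induced by metals, had a median of −0.41 with 11 of 13 below 0, and of −0.24 with quantile normalization. MT1G was at −0.92, MT1F at −0.88 and MT2A at −0.17. Small nucleolar RNA host genes were lower in 13 of 15 cases with a median of −0.36 (−0.24 with quantile normalization), SNHG15 at −0.61 and SNHG9 at −0.55 among them. Families were taken as genes whose symbols share the letters before the first digit. Some are thus only naming prefixes, such as LINC, LOC and FAM. Among 283 families of this kind with at least 8 tested genes 35 lay outside the central 95% of random lists, where 14.2 are expected from families of unrelated genes. Genes of a family may vary together, so this excess does not measure chance. Large ribosomal protein genes had a median of −0.21, where random lists had a middle of −0.11, and of −0.07 with quantile normalization, so its size depended on the scaling. Olfactory receptor genes, dim throughout, were at 0.32, where random lists of like brightness had a middle of 0.22, and at 0.14 with quantile normalization.

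Differentiation and cornified envelope genes were lower as a list, though 18 of its 49 members were above 0. The late cornified envelope (LCE) family, with 13 tested genes, had a median of 0.31 inside the random range. A brightness trend between the arrays was tested by quantile normalization, which left the median at −0.34, still below all random lists, so the trend does not account for it. Defects of single spots were tested against brightness-matched random lists, which carry the same rate of defects and held 0.618 members at 2-fold lower on average, against the 11 seen. Reduced differentiation after NCSTN loss is a hypothesis left untested, since a test needs at least several separately grown cultures per group. Such cultures would still not part NCSTN loss from other effects of the same siRNA. A difference between the 2 cultures unrelated to NCSTN, such as their density, may also give the pattern and cannot be told apart from that hypothesis with 1 array per group.

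Differences of 2-fold crowded among dim probes, more of them higher. Of the 26090 tested probes 24409 were well above background on all scans. They held 474 of the 1110 differences, 249 higher and 225 lower. The other differences were in probes that passed the filter through 1 group only. Of 40 differences of 2-fold seen in single dim spots of 19 repeated probes, 20 stayed past 2-fold in the probe's other spots, but these came from 4 probes. With each probe counted once 17.9% stayed. The other spots had the same sign for 39 of the 40, but 78.4% of all such dim spots were above 0, which gives higher calls their sign without any call. Of the 5 probes with lower calls 4 kept the sign, which is too few probes to decide, so defects of single spots cannot be told apart from differences in the RNA here. A constant background offset between the arrays was removed in a second test, which left 256 of the 349 higher probes in the dimmest of 10 brightness groups while lower probes went from 211 to 308, so the crowding stayed. The excess of higher over lower in that group did not, but the offset was set from the median of those same probes. An offset as the source of that excess therefore cannot be told apart from other sources. In groups 2 to 4, from which the offset was not set, higher against lower went from 121 and 61, 67 and 45, and 44 and 30 to 102 and 93, 60 and 56, and 40 and 36. The median difference in linear signal rose from 3.54 in the dimmest group to 21.9 in group 6. A constant offset alone would give the same value in each, so these medians argue against it as the only source of the shift. A brightness-dependent signal difference between the arrays is a candidate explanation for part of the trend, since the 2 well-measured control probes without a human target were also brighter on the NCSTN siRNA array, by 0.44 on average. An offset would raise them as well. An effect of NCSTN siRNA on weakly expressed genes cannot be told apart from these with 1 array per group.

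Scans of a group shared spot deviations. Repeat scans of 1 hybridised array would need correlations within a group above those across groups, and the lowest within a group was 0.815 after the other group's deviations were taken out, against at most 0.390 across groups. Separate arrays at the same slide position would raise that correlation as well, so it does not part them from repeat scans. Separate arrays of separate cultures at the same slide position would share background-outlier spots about as often as chance gives, and the lowest ratio within a group was 16.8. Non-uniform spots were shared by 3 to 22 spots within a group and by 0 across groups. No biological explanation was tested for this pattern.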
